A study of Mus musculus with 6 samples.

How the data were processed

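Total RNA of 6 samples was measured, each on its own 1-colour Agilent mouse mRNA array: 3 syngeneic heart grafts (C57BL/6 donor and recipient) and 3 allogeneic heart grafts (BALB/c donor, C57BL/6 recipient), all taken on day 5 after heterotopic transplantation. Per the labels' protocols, the hearts were digested with collagenase and passed through a filter, and the RNA was amplified, labelled with Cy3 and hybridised to 1 array per graft. Groups and replicate numbers were taken from the sample titles. The labels name separate grafts, and adjusted p-values therefore refer to the spread between 3 grafts of a group.

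Per the file headers, the deposited spot intensity values came from Agilent Feature Extraction, which the submitters' processing notes give as version 11.0.1.1. The processed intensity of a spot is its background-subtracted and detrended brightness within 1 array, not scaled between arrays, per the file headers. The deposited files also hold the median brightness of each spot and of its local background, and 0 or 1 flags for spots well above background, saturated spots and outliers. The authors also deposited 1 table of normalised values for the same arrays. Its columns were set against each array's processed intensity: Pearson's r across probes with log2 intensity lay between 0.993 and 0.999, so the authors' deposited values are on a log2 scale in the same direction and not centred per gene. The column medians were 6.26 and the 75th percentiles 9.73 on all 6 arrays, and how the authors normalised the table is not given in the sources used here. With it 6925 features rose and 8150 fell in allogeneic grafts, close to 6901 and 8133 with quantile normalization. The authors' table is therefore not an independent check on that scaling.

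Each array held 43020 non-control spots of 39429 probes. Spots flagged as outliers and 1377 control spots were left out, spots of a probe were averaged, and 29 probes without a usable spot on some array were dropped, leaving 39400 probes. Of these, 27218 were named with 1 gene symbol by matching their RefSeq accession, without version, to a gene table of assembly GRCm38.p6. The other 12182 were not named, and none had several symbols. Coordinates are not reported, since the array annotation and the gene table use different assemblies.

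The main values were log2 processed intensity minus each array's 75th percentile of it. Probes well above background on all 3 arrays of at least 1 group were kept (27962 probes), and each gene was represented by its probe with the highest mean, giving 22956 features, 15963 of them with a gene symbol. Among 2889 called features with several probes, 206 had probes called in opposite directions. Groups were compared with limma version 3.58.1 in R version 4.3.3 (linear model, moderated variances, two-sided) and Benjamini-Hochberg adjustment at 0.05. Where a probe was not well above background on any array of a group, its fold is given as a lower bound: the bright group's mean was set against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Such a bound holds for the main values only. Normexp, a background correction described below, gave changes smaller than the bound for many of the named genes that have one. Probes of close paralogs (H2, Gzm, Gbp, Klr, Hba and Hbb, Ifit, histone and paired receptor genes) can share signal, so values of single members of those families are uncertain.

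Before the data were examined, 50 gene lists were fixed for heart and immune cell types, pathways, RNA quality and the study's theme of circular RNA and microRNA. The 46 lists of cell types, pathways, quality and theme with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. The sex, donor strain and housekeeping lists are described by their genes. The named genes were also fixed by rule. They are the 10 largest rises and 10 largest falls among called genes well above background on all 6 arrays, and the 4 largest bounds in each direction. From each list up to 4 called members of largest change were taken, with up to 2 bright members where none passed. All members of the sex and donor strain lists and 3 reference genes (Actb, Gapdh and Hprt) completed the rule. Some genes that the rule takes are not reported here.

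The scripts were tested on simulated data with the real means and spreads of the allogeneic against syngeneic comparison over 22956 features. Of 50 simulated changes each, 6% were recovered at a log2 fold change of 0.5, 66% at 1, 94% at 2 and 98% at 4, and 11 of 22756 unchanged features were called. A simulated shift of 0.5 in 1 list was recovered, and 0 of the other lists were called. Features were drawn independently and few were changed. In the real data, estimated correlations within lists reached 0.70 (cell cycle genes) and most features were called. The simulation therefore does not test list calls under those conditions.

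The alternatives were other scalings (array median, percentile over bright probes, quantile), normexp background correction with an offset of 50, the authors' deposited table, other filters on dim probes, other ways of joining probes, moderated variances with a trend, replicate number or slide as a block, leaving out each array in turn, and, for the lists, no shared members and no H2 genes. Normexp was planned on the mean spot brightness, which the scanner files do not hold, and was run on the median. The scanner files place 4 arrays (3 syngeneic and allogeneic replicate 1) on 1 slide and 2 arrays (allogeneic replicates 2 and 3) on another. Fits within slide 1 alone and with slide as a random block were added after seeing the data. Only slide 1 held both groups, so a fit with slide as a block estimates the same fold changes as a fit within slide 1.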

Results

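Heart grafts transplanted heterotopically, that is, into a recipient that keeps its own heart, were compared on day 5 between 3 syngeneic grafts, in which donor and recipient share a strain, and 3 allogeneic grafts, in which BALB/c hearts were placed in C57BL/6 recipients. The series concerns circular RNA networks in transplant rejection, and its mRNA arrays address which transcripts differ between the 2 kinds of graft. All allogeneic donors were BALB/c and all syngeneic donors C57BL/6, so donor strain is confounded with group. Between 67.3% and 78.5% of probes were well above background on an array, with the highest shares on the 2 allogeneic arrays of slide 2 (78.4% and 78.5%) against 69.5% on allogeneic replicate 1. No spot was saturated, and the number of arrays limits the precision.

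Allogeneic grafts differed from syngeneic grafts across most of the measured transcriptome. Of 22956 features, 6430 rose and 8299 fell in allogeneic grafts, 3409 and 4307 of them by at least 2-fold. The balance of rises and falls depended on the scaling. It was 7174 and 7599 with scaling to the array median, and 5454 and 10388 after normexp with the 75th percentile. The largest rise among genes measured on all arrays was in Gzmb, a protease of cytotoxic granules, which was 2055-fold higher (SE 0.20 on the log2 scale, limma adjusted p = 8.45e-07, n = 3 per group). It was followed by Ccl8, a monocyte-attracting chemokine, with a log2 fold change of 8.91 ± 0.18 (SE), and Plac8, a gene of monocytes and other leukocytes, at 8.56 ± 0.16. The largest falls were in Pcsk6, a proprotein convertase, by 6.55 ± 0.42, and Magix by 6.28 ± 0.17, and Ckm, the muscle creatine kinase, fell by 5.72 ± 0.25. With the mean of a gene's probes the fall of Magix was 3.97. The 3 allogeneic and 3 syngeneic values did not overlap for 71.2% of all features tested, against 10% by chance, and for 99.5% of those called.

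Further rises among the leading genes were in Ccl5, Cfb, Jaml, Cxcl10, Gzma, Ms4a4b and Il1b, from 8.07 to 7.41 on the log2 scale. Further falls were in the carboxylesterases Ces1d and Ces2e, in Kcnv2 (a potassium channel subunit), Vwa3a, Stxbp4 (-3.52 with the mean of its probes), Fmo1 and Efnb3, from 6.24 down to 5.35 in size. Some genes were not well above background on any array of 1 group. Ifng, the cytokine interferon gamma, was at least 976-fold higher in allogeneic grafts, Gbp2b, also a gene of the donor strain list, at least 707-fold, Ubd at least 619-fold and Pdcd1, the PD-1 receptor, at least 401-fold. Lrrc17 was at least 44.9-fold lower, Fmo2 at least 39.6-fold, Lrat, which makes retinyl esters, at least 37.5-fold and Clec18a at least 24.9-fold lower. All of these passed the limma test. Their bounds hold for the main values only, and the smallest changes over the alternatives lay below them. On the log2 scale these were rises of 7.47 for Ifng, 7.44 for Gbp2b, 6.68 for Ubd and 6.19 for Pdcd1. The smallest falls were 2.51 for Lrrc17, 2.57 for Fmo2, 2.61 for Lrat and 1.91 for Clec18a.

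Of the 46 gene lists tested, 26 were higher and 11 lower in allogeneic grafts, and 9 had no call. None of these calls held when the correlation between genes was estimated from the data, where 10 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.0911. With fry, which does not set a list against other genes, 42 lists passed, in data where 14729 of 22956 features were called. The median log2 fold change of all features was -0.12, and -0.23 after normexp with the 75th percentile, so list medians under 0.5 in size are also given relative to it. Normexp moved the log2 fold change of 58 of 198 named genes by over 1.5 times, 57 of them to a change smaller in size. A smaller move on the log2 scale can still be several-fold, so the other genes are not all stable in fold. Where normexp moved a list median by over 1.5 times, values after it are given as a pair, first with quantile normalization and then with the 75th percentile. Bounds of list members hold for the main values only. After normexp with the 75th percentile the log2 rises were 5.22 for Cd3d, 4.84 for Cd3g, 3.28 for Fasl, 2.35 for Klrk1 and 2.94 for Il1r2. Those of Jchain, Gbp8, Xcl1, Il6 and Pdcd1lg2 were 4.42, 4.92, 4.55, 5.33 and 4.64. Each lies below the bound given for that gene. Counts of members adjusted over the list alone were the same as those over all genes unless given. Members that went against their list, or did not pass, are named outside the rule for named genes, after their values were seen.

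**Figure D1:**
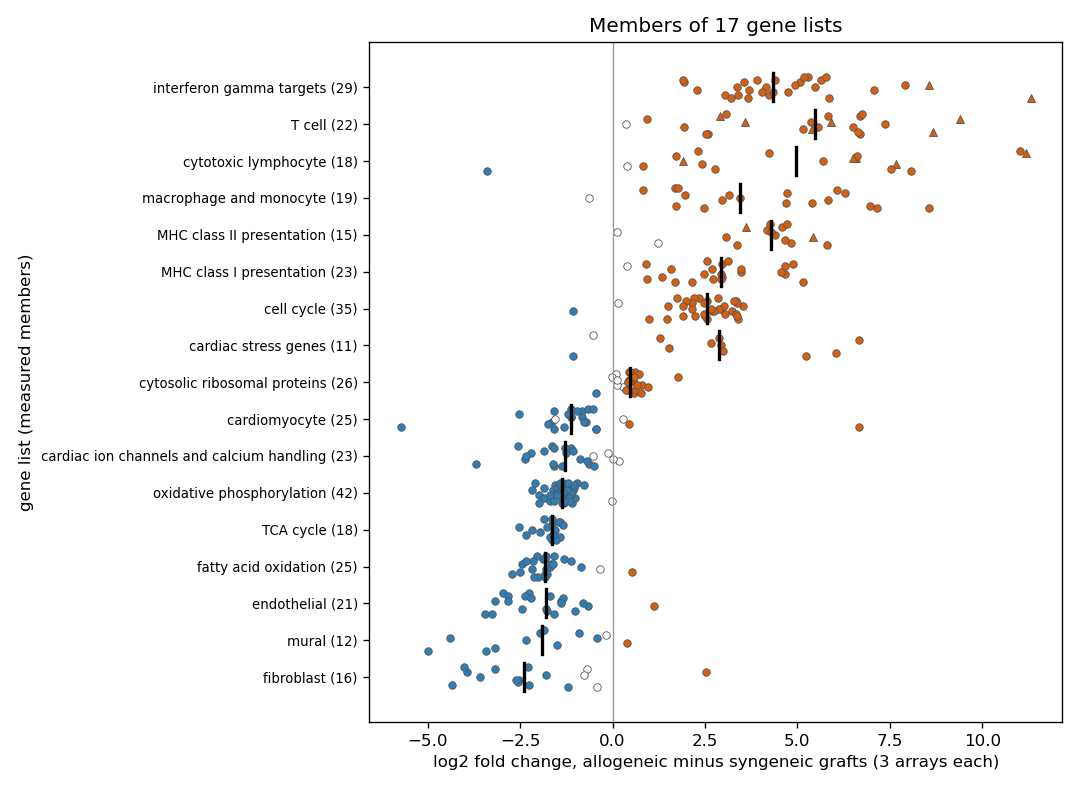
Log2 fold change (allogeneic minus syngeneic, x axis) of each measured member of 17 gene lists (y axis). Filled points passed the limma test, open points did not, triangles mark members not well above background on any array of 1 group (fitted value), and bars mark list medians, from 5.47 for T cell genes to -2.40 for fibroblast genes.

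Most genes of T cells, cytotoxic lymphocytes and NK cells rose. All 15 pan leukocyte genes rose, with a median of 4.46 (4.57 with slide as a block), among them Cytip by 5.82 ± 0.19, Cd52 by 5.45 ± 0.20 and Cd53 by 4.84 ± 0.16 (adjusted p = 0.169 with an estimated correlation). Of 22 T cell genes 21 rose and Cd4 did not pass (0.36). Their median was 5.47, or 5.27 with members at their bounds, 5.21 with slide as a block and 3.71 and 3.55 after normexp (adjusted p = 0.236 with an estimated correlation). The T cell receptor subunits Cd3d and Cd3g were at least 189-fold and at least 188-fold higher, the kinase Lck rose by 6.75 ± 0.22, and Skap1, well above background on 1 of 3 syngeneic arrays, by 7.37 ± 0.25. Of 18 cytotoxic lymphocyte genes 16 rose (17 adjusted over the list alone), including the death ligand Fasl at least 56.1-fold. Gzmm fell by 3.40, and the list median was 4.97, 4.56 with bounds and 4.46 with slide as a block (adjusted p = 0.225 with an estimated correlation). It was 3.02 and 2.82 after normexp, 2.60 with no filter on dim probes and 2.41 with probes above background on all 6 arrays. Among 14 NK cell genes 13 rose, with Il2rb, the interleukin 2 receptor beta chain measured on 1 of 3 syngeneic arrays, up by 7.25 ± 0.29 and the receptor gene Klrk1 at least 19.8-fold higher. The NK list median was 3.89, 2.46 with bounds, 3.08 with slide as a block and 1.37 and 1.17 after normexp (adjusted p = 0.225 with an estimated correlation).

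Most genes of macrophages, monocytes and neutrophils rose. Of 19 macrophage and monocyte genes 18 rose, with a median of 3.43 (3.61 with slide as a block), led by Plac8, the Fc receptor gene Fcgr4 at 7.15 ± 0.12, the lectin gene Clec4d at 6.96 ± 0.21 and Mpeg1 at 6.29 ± 0.16, or 3.41 with the mean of its probes (adjusted p = 0.0911 with an estimated correlation). Of 15 neutrophil genes 12 rose, with a median of 2.18, or 1.07 with bounds, 3.02 with slide as a block and 0.58 and 0.54 after normexp, where 12 and 8 rose (adjusted p = 0.225 with an estimated correlation). The calprotectin genes S100a8 and S100a9 rose by 5.87 ± 0.40 and 5.53 ± 0.39, and Il1r2, the decoy interleukin 1 receptor, was at least 35.8-fold higher. Of 14 dendritic cell genes 8 rose and 6 did not pass, with Itgax up by 6.09 ± 0.30 and the transcription factor gene Irf8 by 4.38 ± 0.13. That list's median was 2.14, 1.60 with bounds and 1.57 with slide as a block (adjusted p = 0.384 with an estimated correlation). It was 0.91 without genes of other lists and 0.85 and 0.66 after normexp, where 6 rose and 3 fell with the 75th percentile. Of 8 plasma cell genes 7 rose, with a median of 1.00 (1.11 with slide as a block, 0.64 and 0.51 after normexp, where 7 and 4 rose), led by Jchain, the joining chain of secreted antibodies, at least 128-fold higher (adjusted p = 0.236 with an estimated correlation). B cell genes had no list call (camera adjusted p = 0.197). Of 14, 6 rose (7 adjusted over the list alone), among them Cd72 by 3.68 ± 0.25, and Bank1, Blnk and Cr2 fell (-1.66, -0.53 and -0.78). The median of 0.50 (0.61 relative to all features) was 0.09 with slide as a block, 0.80 without genes of other lists, 0.27 after normexp with quantile normalization and -0.03 with the 75th percentile, where 5 fell. Lists of mast cell, platelet, and lymph node and thymus genes had no call either, with camera adjusted p of 0.994, 0.726 and 0.423 and medians of -0.30, 0.27 and 0.05, or -0.18, 0.39 and 0.17 relative to all features (-0.61, 0.06 and 0.07 with slide as a block, and the last pair -0.13 and -0.11 after normexp with the 75th percentile). Over the alternatives these medians ranged from -0.61 to -0.15, -0.13 to 0.52 and -0.11 to 0.26. Kit, the stem cell factor receptor gene, rose by 1.22 ± 0.14 and the mast cell protease gene Mcpt4 fell by 2.37 ± 0.25, while 1 of 6 platelet genes fell and 1 of 5 lymph node and thymus genes, Cxcl13, was at least 2.32-fold higher, a call that ended after normexp with the 75th percentile (0.30, limma adjusted p = 0.238, range over the alternatives 8.75e-05 to 0.238).

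Most interferon targets and antigen presentation genes rose, in the same arrays as the pan leukocyte genes (median 4.46). All 29 interferon gamma targets rose, with a median of 4.34 with and without slide as a block, including the chemokine genes Cxcl10 by 7.91 ± 0.13 and Cxcl9 by 7.07 ± 0.14 and the guanylate-binding protein gene Gbp8 at least 184-fold (camera adjusted p = 4.6e-18, adjusted p = 0.115 with an estimated correlation). Of 24 type I interferon targets 21 rose (22 adjusted over the list alone, with 1 lower), with the nucleic acid sensor gene Zbp1 up by 5.99 ± 0.12 and Herc6 by 3.70 ± 0.15. Their median was 2.32 (2.57 with slide as a block; adjusted p = 0.236 with an estimated correlation). In MHC class I presentation 22 of 23 genes rose, with a median of 2.93 (2.99 with slide as a block). The peptide transporter gene Tap1 rose by 4.89 ± 0.16, the immunoproteasome gene Psmb8 by 4.65 ± 0.12 and the transactivator gene Nlrc5 by 4.65 ± 0.16, or 2.52 with the mean of its probes (adjusted p = 0.169 with an estimated correlation). In MHC class II presentation 13 of 15 genes rose (14 adjusted over the list alone), with a median of 4.27, 4.25 with bounds and 3.89 with slide as a block (adjusted p = 0.236 with an estimated correlation). Examples were H2-DMb1 at 5.79 ± 0.23, the class II transactivator gene Ciita at 4.82 ± 0.40 and cathepsin S, Ctss, at 4.72 ± 0.11.

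Most genes of chemokines, their receptors and cytokines rose, again beside the pan leukocyte genes (median 4.46). Of 24 chemokine genes 18 rose and 4 fell, with a median of 3.13 (3.47 with slide as a block), and Xcl1, a lymphocyte chemokine gene, was at least 123-fold higher (adjusted p = 0.225 with an estimated correlation). The chemokine genes that fell were Ccl4, Cxcl12, Cxcl14 and Pf4 (-0.48, -2.36, -1.03 and -1.37). The calls of Cxcl14 and Pf4 ended with slide as a block (-0.35 and -0.51), and that of Cxcl14 also under 3 scalings. Of 18 chemokine receptor genes 13 rose, with Cxcr6 up by 7.27 ± 0.23 and Ccr2 by 6.07 ± 0.22, and the scavenger receptor gene Ackr3 fell by 1.85. That median was 2.61, 2.00 with bounds and 2.13 with slide as a block (adjusted p = 0.236 with an estimated correlation). It was 1.73 without genes of other lists and 1.36 and 1.11 after normexp, where 13 and 9 rose. Among 25 cytokine genes 19 rose (20 adjusted over the list alone) and Il15 fell by 1.56, with Il6 at least 226-fold higher and the lymphotoxin beta gene Ltb up by 6.86 ± 0.22. The cytokine median was 2.70, 2.12 with bounds and 2.73 with slide as a block (adjusted p = 0.187 with an estimated correlation). It was 0.93 and 0.65 after normexp, where 21 and 15 rose, and 0.93 with probes above background on all 6 arrays. Of 24 genes of T cell checkpoints and costimulation 21 rose (22 adjusted over the list alone), with the PD-1 ligand gene Pdcd1lg2 at least 123-fold higher and the checkpoint receptor gene Havcr2 (TIM-3) up by 6.55 ± 0.16. Their median was 3.61, 3.25 with bounds, 3.41 with slide as a block and 2.52 and 2.33 after normexp (adjusted p = 0.191 with an estimated correlation). Of 17 leukocyte adhesion genes 13 rose (14 adjusted over the list alone) and Icam2 fell by 0.86, with a median of 3.27 (3.32 with slide as a block) and the integrin gene Itgb7 up by 5.95 ± 0.15 (adjusted p = 0.169 with an estimated correlation).

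Most cell cycle, cell death and complement genes rose, and the pan leukocyte genes rose in the same arrays (median 4.46). Of 35 cell cycle genes 33 rose and Cenpf, measured on 2 of 3 allogeneic arrays, fell by 1.06 (not passing under 1 scaling or with slide as a block). The median was 2.55 (2.47 with slide as a block), with rises in Birc5 by 3.52 ± 0.36, Cdc6 by 3.38 ± 0.28 and the topoisomerase gene Top2a by 3.36 ± 0.41 (adjusted p = 0.301 with an estimated correlation). All 15 genes of pyroptosis and necroptosis rose, with a median of 2.45 (2.50 with slide as a block), including the DNA sensor gene Aim2 by 4.42 ± 0.17 and caspase 1, Casp1, by 4.10 ± 0.11 (adjusted p = 0.0915 with an estimated correlation). Of 20 apoptosis genes 17 rose and the caspase inhibitor gene Xiap fell by 0.54. Their median was 1.35 (1.42 with slide as a block), with the BH3-only genes Pmaip1 and Bid up by 4.36 ± 0.13 and 3.51 ± 0.11 (adjusted p = 0.115 with an estimated correlation). Of 19 complement genes 13 rose and 4 fell, with complement factor B, Cfb, up by 7.95 ± 0.19 and C3 by 3.51 ± 0.19. Among the 4 that fell were C6 and the regulators Cd55 and Cd59a (-0.50, -1.54 and -2.09), C6 not passing under 1 scaling. The complement median was 1.62, 1.59 with bounds and 1.84 with slide as a block (adjusted p = 0.301 with an estimated correlation).

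**Figure D2:**
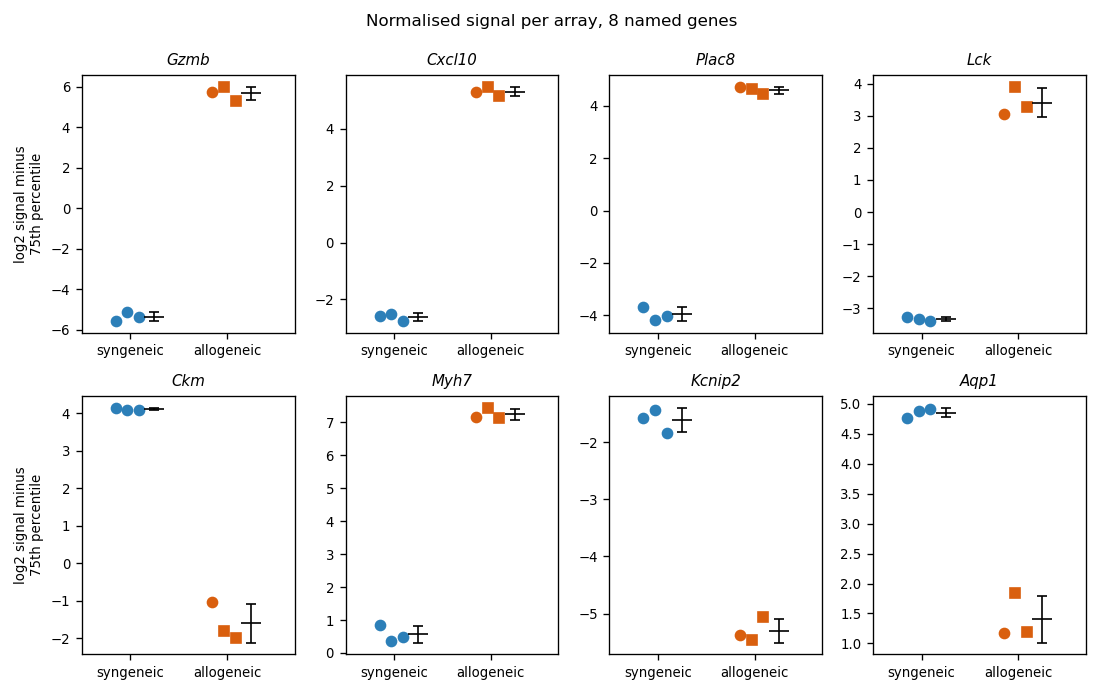
Normalised log2 signal (y axis, each array's 75th percentile subtracted) of 8 named genes on the 3 syngeneic and 3 allogeneic arrays, with group mean ± SD. Circles are arrays of slide 1 and squares arrays of slide 2, and allogeneic replicate 1 on slide 1 lies with the other allogeneic arrays for every gene drawn.

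Most cardiomyocyte genes and genes of cardiac ion channels and calcium handling fell, while most genes of cardiac stress rose. Of 25 cardiomyocyte genes 21 fell, with a median of -1.11 with and without slide as a block, including Ckm, the mitochondrial gene Cox7a1 by 2.53 ± 0.11 and the sarcomere gene Myoz2 by 1.74 ± 0.12 (adjusted p = 0.191 with an estimated correlation). With quantile normalization the median was -0.76, and 16 fell and 3 rose. Myh7, the slow beta myosin heavy chain that is low in the adult mouse ventricle, went the other way and rose by 6.66 ± 0.16 (limma adjusted p = 1.25e-06). The adult alpha myosin gene Myh6 fell by 0.71, a call that ended with quantile normalization (-0.22), and Hspb7 rose by 0.44, which did not pass with slide as a block. Of 23 genes of cardiac ion channels and calcium handling 19 fell and none rose, with a median of -1.27 (-1.21 with slide as a block). They included Kcnip2, a subunit of the transient outward potassium channel, down by 3.68 ± 0.16, and Kcnj11 and Kcnh2, down by 2.54 ± 0.15 and 2.37 ± 0.16 (adjusted p = 0.236 with an estimated correlation). Of 11 cardiac stress genes 9 rose and the skeletal actin gene Acta1 fell by 1.06. Their median was 2.87 (2.71 with slide as a block), with rises in Gdf15 by 6.04 ± 0.40, Timp1 by 5.23 ± 0.42 and the natriuretic peptide gene Nppb by 2.98 ± 0.23 (adjusted p = 0.169 with an estimated correlation). The pan leukocyte genes moved with these lists in the same arrays, with the median of 4.46 given above. So did genes that respond to tissue digestion, of which 15 of 22 rose, with a median of 1.55.

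Most genes of mitochondrial energy metabolism fell, in the same arrays in which the medians of cardiomyocyte and pan leukocyte genes were -1.11 and 4.46. Of 42 oxidative phosphorylation genes 41 fell and Cox8a did not pass (-0.02), with a median of -1.36 (-1.40 with slide as a block) and falls in Uqcrc1 by 2.16 ± 0.14, Cyc1 by 2.10 ± 0.24 and Ndufa9 by 2.00 ± 0.17 (camera adjusted p = 1.93e-11, adjusted p = 0.191 with an estimated correlation). All 18 TCA cycle genes fell, with a median of -1.63 (-1.55 with slide as a block), including Dlat by 2.52 ± 0.18 and Idh3b by 2.33 ± 0.18 (adjusted p = 0.236 with an estimated correlation). Of 25 fatty acid oxidation genes 23 fell and Cpt1a, of the mitochondrial import step, rose by 0.52, with a median of -1.83 (-1.59 with slide as a block). Ppara, the nuclear receptor that drives these genes, fell by 2.71 ± 0.20 and Acadm, the medium-chain acyl-CoA dehydrogenase, by 2.45 ± 0.27 (adjusted p = 0.301 with an estimated correlation). The glycolysis list had no call (camera adjusted p = 0.147), with 8 genes up, 9 not passing and Aldoa, Ldhb, Pfkm and Slc2a4 down among 21, Aldoa not passing under 2 scalings (-0.16 with quantile normalization). The lactate exporter gene Slc16a3 rose by 5.21 ± 0.15, the regulator gene Pfkfb3 by 3.97 ± 0.16 and the glucose transporter gene Slc2a3 by 3.01 ± 0.14, whereas Slc2a4, the insulin-responsive glucose transporter of muscle, fell by 3.02 ± 0.15. The list median was 0.20, or 0.31 relative to all features and 0.09 with slide as a block. With quantile normalization the list passed as higher, as it did after normexp and with the authors' table (adjusted p = 0.0394 with quantile normalization, range over the alternatives 0.0211 to 0.397).

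Most genes of the vessel wall, fibroblasts, nerves and resident macrophages fell, beside the same shifts of cardiomyocyte and pan leukocyte genes (-1.11 and 4.46). Of 21 endothelial genes 20 fell and Ly6c1 rose by 1.12, with a median of -1.81 (-1.84 with slide as a block). The water channel gene Aqp1 fell by 3.45 ± 0.20 and the receptor genes Tek and Kdr by 3.25 ± 0.26 and 3.19 ± 0.30, with Kdr at -1.97 as the mean of its probes (adjusted p = 0.301 with an estimated correlation). Of 12 mural genes, those of pericytes and smooth muscle, 10 fell and Cspg4 rose by 0.41 (not passing with slide as a block). The median was -1.90 (-2.004 with slide as a block), with Rgs5 down by 4.98 ± 0.33 (adjusted p = 0.225 with an estimated correlation). Of 16 fibroblast genes 12 fell and 1 rose, with a median of -2.40 (-1.77 with slide as a block). Among those that fell were Pi16 by 4.33 ± 0.44 and the matrix gene Dpt by 3.93 ± 0.55 (adjusted p = 0.422 for the list with an estimated correlation). The fibroblast gene that rose was Thy1, by 2.53, and Col1a1, Col1a2 and Col3a1 did not pass (-0.41, -0.70 and -0.77). Of 11 Schwann and neuronal genes 8 fell and Cnp rose by 1.24. Their median was -2.05 (-1.73 with slide as a block, -0.64 and -0.95 after normexp), with falls in Cdh19 by 4.14 ± 0.19 and the noradrenaline-making enzyme gene Dbh by 2.85 ± 0.22 (adjusted p = 0.301 with an estimated correlation). Of 12 resident macrophage genes 9 fell and 2 rose, with Cbr2 down by 5.12 ± 0.17, Lyve1 down by 2.57 ± 0.19 and Siglec1 up by 1.83 ± 0.31 beside Timd4 at 0.88, not passing with slide as a block (adjusted p = 0.374 with an estimated correlation). The resident macrophage median of -1.48 moved to -0.86 with slide as a block, and its call ended there (camera adjusted p = 0.0981, range over the alternatives 0.00438 to 0.374) and with probes above background on all 6 arrays (-1.31). Of 10 erythroid genes 8 fell, with a median of -1.55 (-1.72 with slide as a block) and the globin genes Hba-a1 and Hbb-bt down by 1.87 ± 0.21 and 1.75 ± 0.23 (adjusted p = 0.397 with an estimated correlation). Adipocyte genes had no call (3 of 5 fell, median -1.03, -1.99 with slide as a block, -0.69 and -0.68 after normexp, where 3 and 5 fell, -0.57 with no filter on dim probes, camera adjusted p = 0.214). Of 4 measured epicardial and mesothelial genes, too few to test as a list, Krt18 rose by 5.97 ± 0.35, well above background on 2 of 3 syngeneic arrays, and Wt1 fell by 1.24 ± 0.18.

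Matrix, coagulation and stress genes moved in both directions, while pan leukocyte genes had a median of 4.46 and cardiomyocyte genes of -1.11. Of 31 genes of extracellular matrix and fibrosis 13 rose, 11 fell (13 adjusted over the list alone) and 7 did not pass. Their median of -0.64 and mean of 0.42 differ in sign, and the test pointed upwards without passing (camera adjusted p = 0.364), but it passed with slide as a block (median 0.11, 13 up and 6 down, adjusted p = 0.0205, range over the alternatives 0.0205 to 0.967). Without allogeneic replicate 3 the median was -0.16. The protease gene Adam8 rose by 5.89 ± 0.14, while the gelatinase gene Mmp2 fell by 4.51 ± 0.73 (-2.97 with slide as a block). Of 18 genes of endothelial activation and coagulation 11 rose, and F3, Nos3, Tfpi, Thbd and Vwf fell (-1.59, -0.85, -1.75, -2.61 and -2.81). Among the rises were Ptgs2, the cyclooxygenase 2 gene measured on 1 of 3 syngeneic arrays, by 5.75 ± 0.16, and Plaur by 4.08 ± 0.14. The median was 1.84, 1.38 with bounds, 1.97 with slide as a block, 0.90 and 0.77 after normexp and 1.15 with probes above background on all 6 arrays (adjusted p = 0.301 with an estimated correlation), and the call ended when genes held by other lists were left out (median 0.33, camera adjusted p = 0.216, range over the alternatives 0.00201 to 0.301). Of 19 hypoxia and oxidative stress genes 11 rose, and Ankrd37, Ddit4, Sod2 and Vegfa fell (-1.26, -1.96, -1.04 and -1.32), Vegfa not passing with slide as a block. The list had a median of 1.11 (1.14 with slide as a block), with Hmox1, the haem oxygenase gene, up by 4.31 ± 0.28 and Car9 by 4.11 ± 0.39 (adjusted p = 0.384 with an estimated correlation).

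Genes that respond to tissue digestion, and common reference genes, also differed between the groups, beside the same pan leukocyte and cardiomyocyte medians (4.46 and -1.11). Of 22 dissociation stress genes 15 rose and Hspa8, Klf2 and Klf4 fell (-0.47, -1.26 and -2.07), with the sign of Hspa8 turned under quantile normalization (0.0079). The list median was 1.55 (1.36 with slide as a block, 1.09 and 0.96 after normexp), and rises included the immediate early genes Fos by 3.81 ± 0.30, Egr2 by 3.65 ± 0.28 and Atf3 by 3.28 ± 0.13 (adjusted p = 0.169 with an estimated correlation). Of 26 cytosolic ribosomal protein genes 20 rose and Rps2 fell by 0.44. The median was 0.48, or 0.59 relative to the median of all features, and 0.36 with slide as a block, where 9 rose and none fell (adjusted p = 0.397 with an estimated correlation). Rpl3 rose by 1.78 ± 0.12 and Rps19 by 0.96 ± 0.12. Among 15 housekeeping genes 7 rose and 1 fell, with B2m, the MHC class I light chain gene, up by 2.14 ± 0.11 and Sdha, a mitochondrial enzyme gene, down by 1.84 ± 0.12. Actb rose by 0.81 ± 0.11 (1.34 with quantile normalization) and Hprt by 0.93 ± 0.12, while Gapdh did not pass (-0.41 ± 0.15, limma adjusted p = 0.0506). Gapdh passed as lower with the mean of its probes (-0.60, limma adjusted p = 0.00405, range over the alternatives 0.00405 to 0.466). It also passed with a variance trend, with probes above background on all 6 arrays, with slide as a random block, and without syngeneic replicate 2 or allogeneic replicate 2 (-0.54 and -0.48), and its sign turned with quantile normalization (0.09).

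The lists fixed for the study's theme had no call by camera. Both passed with fry (adjusted p = 0.00021 for microRNA machinery and 0.00156 for circular RNA genes), as did 42 of 46 lists. Of 17 microRNA machinery genes 9 fell, Ago2 and Xpo5 rose by 0.37 and 0.40 and 6 did not pass, with a median of -0.47, -0.36 relative to all features -0.43 with slide as a block and -0.18 and -0.43 after normexp (camera adjusted p = 0.11). The Argonaute gene Ago4 fell by 1.54 ± 0.09, the silencing cofactor gene Tnrc6c by 1.51 ± 0.15, and the processing enzyme genes Dicer1 and Drosha by 0.91 ± 0.13 and 0.80 ± 0.13. Of 21 genes of circular RNA biogenesis and turnover 9 rose, 9 did not pass, and Ilf2, Qk and Rbm20 fell (-0.50, -0.84 and -1.45), Ilf2 and Rbm20 not passing with slide as a block. The median was 0.30, or 0.42 relative to all features, 0.29 and 0.18 after normexp and 0.11 with the mean of probes (camera adjusted p = 0.0722). Eif2ak2 (PKR), a kinase that binds double-stranded RNA, rose by 1.94 ± 0.14 and the RNA-editing enzyme gene Adar by 1.60 ± 0.14. This list passed as higher with slide as a block (median 0.36, adjusted p = 0.0312), after normexp with the 75th percentile, with no filter on dim probes and without allogeneic replicate 3 (median 0.34, adjusted p = 0.0469, range over the alternatives 0.0231 to 0.384).

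Genes of the sex and donor strain lists differed between the groups. All samples carry the label male, yet Ddx3y, a Y-linked gene, was not well above background on any of the 3 syngeneic arrays and was at least 26.6-fold higher in allogeneic grafts. After normexp its log2 rise was 2.68 with quantile normalization and 2.45 with the 75th percentile, below that bound. Eif2s3y, also Y-linked, rose by 3.74 ± 0.12 and was well above background on all arrays, and Uty was at least 1.82-fold higher, a call that ended after normexp with the 75th percentile (-0.040). The X-linked Xist, which is expressed from the inactive X chromosome, was measured on all 6 arrays and was lower in allogeneic grafts by both of its probes, by 1.42 ± 0.12 for the brighter. After normexp with quantile normalization its log2 fold change was -0.74. The Kdm5d probe was not well above background on any array. Of the donor strain genes, Gbp2b was at least 707-fold higher in allogeneic grafts. Ifi202b, well above background on 1 of 3 syngeneic arrays, rose by 11.04 ± 0.76, or by 7.23 after normexp with the 75th percentile. Its other probe was not well above background on any syngeneic array. Both strain genes rose in the same arrays as all 29 interferon gamma targets (median 4.34). Their rises could therefore not be assigned to donor strain apart from the other differences between the groups.

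**Figure D3:**
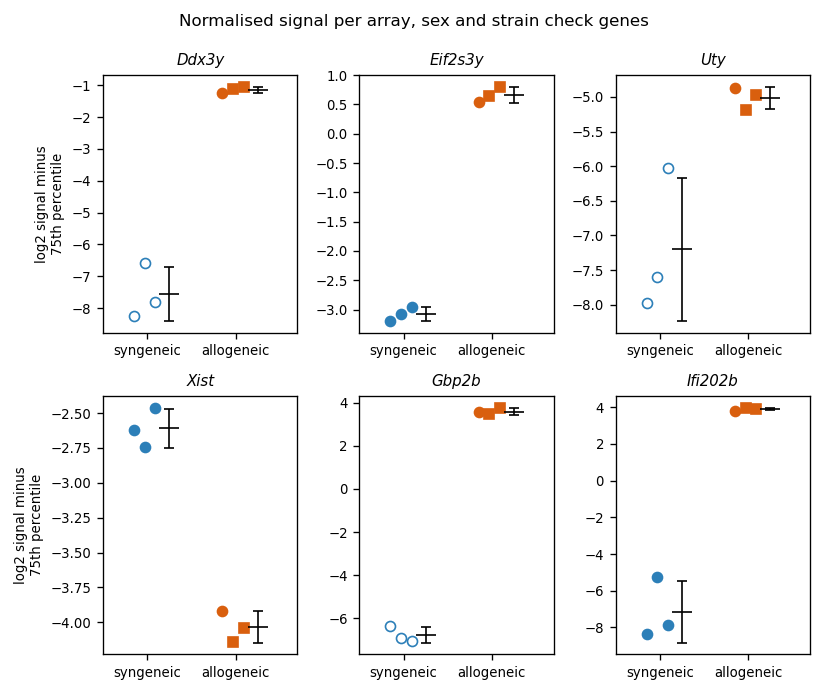
Normalised log2 signal (y axis, each array's 75th percentile subtracted) of 4 sex check genes and 2 donor strain check genes on each array, with group mean ± SD. Circles are slide 1, squares slide 2 and open symbols mark groups in which the probe was not well above background on any array, as for Ddx3y, Uty and Gbp2b in syngeneic grafts.

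Array correlations across genes were at least 0.994 within syngeneic grafts, at least 0.987 within allogeneic grafts and between 0.880 and 0.890 across groups, and the first principal component held 90.3% of the variance. With slide as a block 5199 features rose and 8357 fell, and within slide 1, where allogeneic replicate 1 alone met the 3 syngeneic arrays, 5621 rose and 9066 fell. That lone array was assumed to vary like the 3 syngeneic ones, which alone gave the spread. With that block 220 features were higher and 42 lower on slide 2, which held allogeneic grafts only.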

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

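Fits within slide 1 and with slide as a random block were chosen after seeing the data. All other settings were fixed before, except that normexp was changed from the mean to the median spot brightness once the files were read. Counts of called features stayed within 1.5 times the main value in all settings except 2: features at least 2-fold lower numbered 2658 after normexp and quantile normalization, and features at least 2-fold higher 2201 after normexp and the 75th percentile. Normexp adds an offset that compresses dim values, and whether that is the cause was not tested. With an estimated correlation, 0 lists were called higher and 0 lower by camera (10 at an unadjusted p under 0.05). Fry, which passed 42, does not set a list against other genes, so the 2 results answer different questions. Leaving out each array in turn gave 5582 to 6952 features higher and 7018 to 8501 lower. With slide as a random block (correlation 0.292), 5982 were higher and 8254 lower. Of 198 named genes, 188 kept direction and side of the threshold in all 21 settings that gave them a value, as did 41 of 46 lists in 22 settings without the estimated correlation. Hpgds (-0.018) and Uty (-0.040) reversed without passing after normexp and the 75th percentile, and the cause was not tested. Calls ended when 1 array was left out for Cpa3 (syngeneic 1 or 2, allogeneic 1 or 2; adjusted p up to 0.117), Hpgds (syngeneic 1 or 3; up to 0.0686) and Cfd (syngeneic 1 or 2; up to 0.0638). With slide as a block, the calls of the named genes Hpgds (0.36), Cfd (-2.06), Derl3 (2.03), Car3 (-1.99) and Rbm20 (-0.93) ended, as did, outside the rule for named genes, those of Cxcl14, Pf4, Cenpf, Hspb7, Cspg4, Timd4, Vegfa, Rps2 and Ilf2. Within slide 1 that of Uty ended. Calls also ended for Cpa3 after normexp and quantile normalization, with no filter on dim probes and with a replicate block, and for Derl3 and Cxcl13 after normexp and the 75th percentile. The series' design text speaks of pairs of grafts without saying what joins a pair. Deviations of arrays that share a replicate number correlated at -0.05, -0.16 and -0.11. With 3 arrays per group these values cannot show whether the grafts are paired, and the main fit used no pairing. With a replicate block 5786 features were higher and 7383 lower. Signal over background limits dim genes: 911 called features have only a bound.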

Other observations

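Gene families defined by symbol after the comparison had been seen added further groups, tested with camera over 22 families on the same arrays, in which pan leukocyte genes had a median of 4.46. Pattern recognition and myeloid receptor families rose: 11 of 12 Toll-like receptor genes (median 2.58, 2.46 with bounds, 1.61 and 1.53 after normexp with quantile normalization or the 75th percentile, where 9 rose; adjusted p = 0.183 with an estimated correlation), with Tlr1 up by 5.43 ± 0.15 and Tlr6 by 4.65 ± 0.13. Of 28 paired immunoglobulin-like receptor genes 21 rose and 2 fell (median 2.42, 1.88 with bounds, 0.94 and 0.67 after normexp; adjusted p = 0.183 with an estimated correlation), led by Pira2 at 6.84 ± 0.14. Of 13 SLAM and GIMAP genes, which act in leukocytes, 12 rose (median 1.76; adjusted p = 0.261 with an estimated correlation), and Slamf8 was at least 210-fold higher. Of 49 proteasome genes 25 rose and 4 fell, with the 3 immunoproteasome catalytic subunits Psmb8, Psmb9 and Psmb10 up by 4.65, 4.55 and 3.12 and the family median at 0.35, or 0.46 relative to all features (2 fell with slide as a block; adjusted p = 0.26 with an estimated correlation). Of 17 tRNA ligase genes 12 rose and none fell, led by the interferon-inducible Wars at 1.91 ± 0.17 (median 0.73; adjusted p = 0.26 with an estimated correlation). Among 18 septin and tubulin genes 12 rose and 5 fell, and Tubb3, best known from neurons, rose by 7.03 ± 0.17, although 8 of 11 Schwann and neuronal genes fell (family median 0.85; adjusted p = 0.392 with an estimated correlation).

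Families that fell included mitochondrial ribosomal proteins (60 of 77 fell, 3 rose, or 54 and 1 with slide as a block, median -0.63; adjusted p = 0.392 with an estimated correlation), glutathione S-transferases (14 of 20 fell, 2 rose, median -1.49; adjusted p = 0.26 with an estimated correlation) and protocadherins (24 of 35 fell, 2 rose, median -0.91, -0.41 after normexp with quantile normalization; adjusted p = 0.273 with an estimated correlation). Gsta3 fell by 5.25 ± 0.51 and the vascular endothelial Pcdh12 by 4.81 ± 0.29. Of 31 collagen genes 20 fell and 1 rose, or 12 and 0 with slide as a block (median -0.92; adjusted p = 0.392 with an estimated correlation). Among long noncoding RNAs, Mhrt, transcribed antisense within the Myh7 locus, fell by 4.30 ± 0.20 while Myh7 rose by 6.66 ± 0.16, and Mirt1 and Mirt2, first described in infarcted hearts, were higher. Mirt1 rose by 4.12 ± 0.18 with 1 of 3 syngeneic arrays well above background, and Mirt2 was at least 19.0-fold higher. None of the families named so far changed the sign of its median under the scalings tried. With slide as a block the medians were 2.96, 2.41, 1.77, 0.43, 0.74 and 0.58 for the families that rose, in the order given, and -0.65, -1.40, -1.17 and -0.68 for those that fell.

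Camera called 6 further families. Zinc finger proteins were lower (194 of 352 fell, 44 rose, median -0.46, -0.35 relative to all features; adjusted p = 0.26 with an estimated correlation), as were potassium channels (35 of 61 fell, 10 rose, median -0.51, -0.90 with slide as a block, -0.29 after normexp with quantile normalization; adjusted p = 0.443 with an estimated correlation). Schlafen proteins (5 of 7 rose, median 3.39), C-type lectins (15 of 26 rose, 7 fell, median 1.44, 0.78 and 0.55 after normexp) and translation initiation factors (21 of 54 rose, 10 fell, or 19 and 6 with slide as a block, median 0.20, 0.32 relative to all features) were higher, each with an adjusted p of 0.26 with an estimated correlation. Replication histones were called higher too (20 of 40 rose, 9 fell, median 0.51, 0.38 with bounds, 0.17 with slide as a block; adjusted p = 0.613 with an estimated correlation), but their median turned to -0.019 after normexp with the 75th percentile. Cytochrome P450 enzymes, carboxylesterases, semaphorins and plexins, Wnt ligands and Frizzled receptors, ADAM proteases and TRIM proteins had no call.

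The tests of Ddx3y and of the cardiomyocyte genes were chosen after the patterns had been seen. The Y-linked Ddx3y was not well above background on 3 of 3 syngeneic arrays although all samples are labelled male. Weaker detection on those arrays was argued against, since of 1345 probes as bright as Ddx3y on the allogeneic arrays (within 0.25 on the log2 scale) 97.6% were well above background on all syngeneic arrays. Another candidate explanation is donor hearts without a Y chromosome that received leukocytes with one. The Ddx3y bound of 4.74 lay within the range of the pan leukocyte rises (0.97 to 5.82), but its fitted rise of 6.41 lay above it. A lower bound cannot place the rise within that range. After normexp the Ddx3y rise was 2.68 with quantile normalization and 2.45 with the 75th percentile, while the pan leukocyte range is of the main values. Eif2s3y, also Y-linked, was well above background on all 3 syngeneic arrays. Of the X-linked genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x, chosen after Ddx3y had been seen, only Kdm6a passed (-0.72, limma adjusted p = 0.00562). Xist was higher in syngeneic grafts by only 1.42, or 0.74 after normexp with quantile normalization. On the syngeneic arrays its signal was at percentile 56.6 of all probes, and no array of known sex was measured to set that level against. Whether the donor hearts lacked a Y chromosome therefore stays open.

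Cardiomyocyte genes fell by a median of 1.11. A lower share of heart muscle RNA alone was expected to lower all members alike. The interquartile range of their log2 fold changes was 6.71 times their median SE (0.91 against 0.14), with Ckm and Myh7 far out on opposite sides. The members thus changed by unequal amounts. Their SE measures the spread between grafts and not differences between probes, so the ratio cannot decide about a lower share. A difference between slides was argued against, since the median was -1.11 between arrays of slide 1 alone. A lower share, a change of expression within the muscle cells and the donor strain may each contribute and were not tested apart.

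The 6 arrays form 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 6430 features higher and 8299 lower, and 3409 and 4307 at least 2-fold. The highest count of another split was 0 by limma, with 39 to 213 features at an unadjusted p under 0.05 against 15551 in the real split, so 1 of the 10 splits reached the real value for each. For lists, other splits gave up to 28 in either direction, against 26 higher and 11 lower in the real split, and 3 and 10 of the 10 splits reached these counts when the larger direction of each was taken. Every other split set 2 arrays of a group against 1 and so held part of the group difference, also in its spread. That leaves the feature counts and the list counts without a chance reference.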
